A study of Caenorhabditis elegans with 12 samples.

How the data were processed

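RNA from dissected adult germ lines of Caenorhabditis elegans grown at 20 °C was compared on 12 two-colour arrays. Per the labels, each array carried RNA of 1 mutant sample and 1 wild-type sample. The 3 groups were mes-2 mutants, mes-4 mutants and mes-2; mes-4 double mutants, with 4 arrays each, and the replicates were harvested independently. In every group the mutant RNA carried Cy5 on 2 arrays and Cy3 on 2 arrays. The wild type was strain N2 for mes-4, and unc-4(e120) for mes-2 and for the double mutant. Per the labels' protocols, germ lines of wild type and of the single mutants came from adults with at most a few fertilized embryos, whereas for the double mutant well proliferated germ lines with oocytes were selected. Per the same protocols, RNA was extracted with Trizol, poly-A RNA was amplified, and the amplified RNA was labelled with Cy3 or Cy5 and fragmented.

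The authors deposited 1 log ratio per probe and array, for 22490 probes, and these deposited values were read as log2 ratios. The labels state neither the log base, the normalization, the filtering of spots nor the direction of the ratio. The values ran from -9.31 to 9.15, which excludes log10 for a scanner of usual range but not the natural logarithm, so every fold given rests on base 2. Array medians lay between -0.01 and 0.02. Channel 1 was the mutant on every array and the titles name the mutant before wild type, so positive values were taken as higher in the mutant. The mes-2 probe lay below 0 on all 8 arrays with a mes-2 mutant channel, in either dye orientation. For the mes-4 arrays the direction rests on the labels, those of the dyes included. Arrays of different groups correlated at r = 0.092 to 0.692 in the same dye orientation (24 pairs). In opposite orientation they correlated at -0.144 to 0.46. If the dye labels hold, this argues against a ratio reversed in mes-4 alone. Arrays give no read depth, and their number limits the precision. Between 17297 and 21879 probes had a value on an array, and 288 probes had none on any array.

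Probe IDs were paired with genes through the platform annotation supplied with the series. Of the probes, 17461 named 1 gene, 0 named several and 5029 named none. A gene table of assembly WBcel235 was used only for names, chromosomes, the order of neighbouring genes and the annotated gene span, and it matched 17371 gene IDs and left 90 unmatched. Probes of the same gene were averaged per array. Genes with a value on at least 3 of 4 arrays in every group were tested, which left 12887 genes, 1697 of them on the X chromosome, 11133 on autosomes and 57 without a chromosome. Of these, 819 had more than 1 probe and 11413 had a value on all 12 arrays. Probes without a gene name were left out of the comparisons.

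All 12 arrays entered a single fit per gene with limma 3.58.1 in R 4.3.3, with a coefficient per group and a term for the dye of the mutant RNA. The 3 mutants were each tested against 0, followed by the 3 differences between mutants and the departure of the double mutant from the sum of the single mutants, each refitted with its own parameters so that missing values were handled exactly. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Errors of log2 ratios are limma standard errors (SE) unless an SD is named. Calls were compared with chromosomes by two-sided Fisher's exact tests, adjusted over 12 tests per comparison, and calls of 2 mutants with each other by the same test per direction. Genes are not independent replicates, so these tests describe the genes measured. For each array, the median of X-linked genes minus the median of autosomal genes was taken, tested per mutant by an exact sign-flip test and between mutants by an exact permutation test, both two-sided.

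The 27 gene lists covered complexes, germline functions, somatic tissues that a dissection can carry along and gene families, and 26 of them had at least 5 measured members. They were tested with camera at a preset correlation of 0.01, on limma's moderated statistics because genes with missing values do not pass through the standard form, and adjusted over the lists of a comparison. The test was repeated with the correlation estimated within each list on the genes with all values. Named genes were mes-2 and mes-4, the 8 called genes with the highest and the 8 with the lowest log2 ratio that lay on the same side of 0 on every array of the group and had a gene symbol, 2 members of each list past its test and of the sheath, early embryonic, oocyte and sperm lists, and for each difference the 5 largest called each way. Other members named as examples of a list were picked after their values were seen. The groups, tests, covariates, gene lists, rule for named genes and most other settings tried were set before the data were examined.

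The procedure was tested on simulated data with 12887 genes, of which 200 were changed. The simulated noise was independent between genes and arrays, unlike the real residuals described below, so the shares of recovered and false calls need not hold for these data. In the simulated mes-2 comparison it recovered 38.8% of changes of 0.5 on the log2 scale, 83.6% of changes of 1 and 98.5% of changes of 2, with 7% of calls false. The shares were 34.3%, 73.1% and 89.4% for mes-4, with 3.7% of calls false, and 34.3%, 73.1% and 95.5% for the double mutant, with 6.2% false. The other settings tried were a fit without the dye term, with the replicate number as a block, and on only the groups compared; centring or scaling of the arrays; other filters on missing values; each probe alone; robust moderation; an added 1.5-fold threshold; an overlap at an adjusted p under 0.1; means in place of medians; and leaving out each replicate. A dye term per group, permutations within dye and the removal of arrays with extreme residuals were added after seeing the data. Figures were drawn with matplotlib 3.10.9.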

Results

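The data compare gene expression in dissected germ lines of mes-2, mes-4 and mes-2; mes-4 mutant worms with wild-type germ lines on 12 two-colour arrays, 4 for each mutant. MES-2 is the histone H3 lysine 27 methyltransferase of the Polycomb group in C. elegans, and MES-4 is a histone H3 lysine 36 methyltransferase. Each value is a log2 ratio of mutant over wild type within an array, as read from deposited log ratios whose base and direction the labels do not state. Arrays of the same dye orientation correlated across genes at r = 0.564 to 0.589 within the mes-2 group, 0.381 to 0.724 within mes-4 and 0.348 to 0.559 within the double mutant. For arrays of opposite dye orientation the ranges were -0.124 to -0.026, -0.003 to 0.206 and 0.063 to 0.575. The dye term passed the threshold for 4125 of 12887 genes, and each group was balanced for dye. After the fit 47% of the residual variance lay along a single axis, which set mes-4 replicate 3 and double mutant replicates 1 and 4 apart from double mutant replicates 2 and 3. Along it the histone, intestinal, collagen, major sperm protein, ribosomal and mitochondrial lists lay at percentile 100 of random lists, and the small RNA and cell cycle lists at percentile 0.

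The mes-2 comparison addresses which germline genes depend on the H3 lysine 27 methyltransferase. The probe of mes-2 itself fell to a log2 ratio of -2.80 (SE 0.20, n = 4, limma adjusted p = 2.2e-05). unc-31, which acts in dense-core vesicle release, rose by 2.90 (SE 0.22, n = 4), gpa-1, a G protein alpha subunit, by 3.23 (SE 0.24, n = 4), nrx-1, the neurexin gene, by 3.00 (SE 0.47, n = 4), and gcy-19, a receptor guanylyl cyclase gene, by 3.30 (SE 0.39, n = 3). cls-1, a microtubule-binding CLASP gene, rose by 2.97 (SE 0.34, n = 4). homt-1, an O-methyltransferase gene, fell to -4.65 (SE 0.23, n = 4), an adjusted p of 3.7e-06. The F-box genes fbxa-193, fbxa-108, fbxa-107 and fbxa-192 fell to -4.72, -3.94, -2.61 and -2.57 (SE 0.26, 0.24, 0.24 and 0.16, n = 4 each). These belong to a family of similar sequences, for which array probes can cross-hybridise. phf-14, a PHD finger gene, fell to -2.37 (SE 0.12, n = 4). In the double mutant, compared with the same wild-type strain, phf-14 had -0.47, 0.29, -0.19 and -0.05 on its arrays, homt-1 -0.38 and fbxa-192 0.28. fbxa-193, fbxa-108 and fbxa-107 had -1.31, -1.13 and -1.86 there. The double mutant thus did not share the falls of phf-14, homt-1 and fbxa-192 at their size in mes-2, and their dependence on MES-2 stays open. The mes-4 probe had a value of 0.10 (SE 0.24, adjusted p = 0.909).

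**Figure D1:**
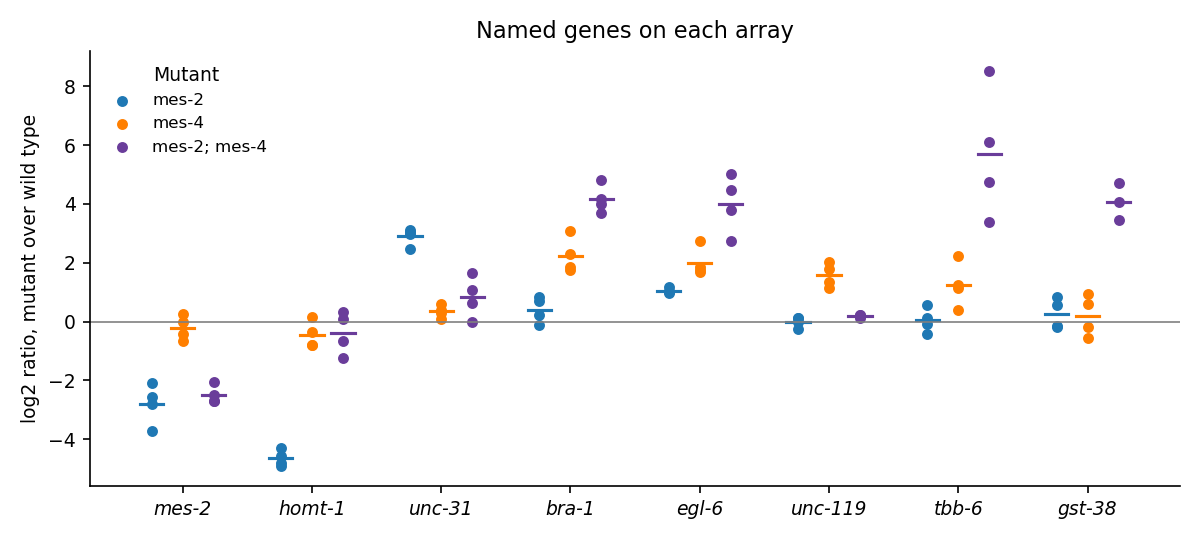
Log2 ratio of mutant over wild type (vertical axis) of 8 named genes on each array, with a dot per array and a bar for the mean of a mutant. The mes-2 probe lay at a mean of -2.80 in mes-2 and -2.49 in the double mutant, and tbb-6 reached 8.54 on 1 array of the double mutant.

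In all, 676 genes passed the threshold in mes-2, 508 higher and 168 lower, and 222 of the higher and 36 of the lower genes differed more than 2-fold. Genes higher in mes-2 were over-represented on chromosome IV, which held 109 of 505 called genes (21.6%, odds ratio 1.46, Fisher's exact adjusted p = 0.00994). On X lay 58 of the 505 (11.5%, against 13.2% of genes tested, adjusted p = 0.437), and 10 of 166 lower genes (adjusted p = 0.0225). The share of higher genes on X was 18.3% when the mes-2 arrays alone were fitted and 18.2% without the 3 arrays at the high end of the residual axis. Without mes-2 replicate 1, 2, 3 or 4 the count of called genes was 408, 352, 413 or 439. It was 402 without the dye term.

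Histone genes rose as a list in mes-2, with 6 of 31 measured members higher, 0 lower and 25 not past the test, and 10 higher when adjusted over the list alone (camera adjusted p = 9.1e-04, adjusted p = 0.917 with an estimated correlation). The examples his-62 and his-59 rose by 0.85 (SE 0.16, n = 4) and 0.83 (SE 0.17, n = 4), and htz-1, the histone H2A.Z gene, rose by 1.27 (SE 0.31, n = 4). Histone probes can cross-hybridise between gene copies. Genes of dosage compensation and X counting rose as a list (adjusted p = 0.0299, adjusted p = 0.917 with an estimated correlation), with 1 of 12 members called over all genes and 1 when adjusted over the list alone. That member was sdc-3, which acts in sex determination and dosage compensation and rose by 1.40 (SE 0.09, n = 4), while the X-linked sdc-1 had 0.84 (SE 0.36, adjusted p = 0.269). Cytoplasmic ribosomal protein genes fell as a list (adjusted p = 0.0271, adjusted p = 0.917 with an estimated correlation), with 0 of 67 members called over all genes and 0 when adjusted over the list alone. Their examples rpl-37.2 and rps-14 had -0.52 (SE 0.17, adjusted p = 0.116) and -0.35 (SE 0.13, adjusted p = 0.19). The dosage compensation and ribosomal lists lost the call without mes-2 replicate 2 or without mes-2 replicate 4, when only 1 list passed. With the replicate number as a block the dosage compensation list lost it as well.

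Of the sperm genes outside the major sperm protein family, 2 of 17 rose in mes-2 (2 when adjusted over the list alone), namely fog-3, which directs germ cells to the sperm fate, by 0.72 (SE 0.08, n = 4) and spe-15 by 0.75 (SE 0.16, n = 4). The list itself did not pass (adjusted p = 0.285). Of 20 neuronal genes 2 rose, unc-31 and ric-19, the latter by 1.95 (SE 0.203, n = 4), and of 84 neuropeptide genes 3 rose, among them nlp-40 by 1.52 (SE 0.079, n = 4), with the same counts when adjusted over the list alone and no pass for either list (adjusted p = 0.0671 and 0.433). The neuronal list passed without the dye term, without mes-2 replicate 1 or 3, and without any single replicate of the double mutant. Nuclear hormone receptor genes had 9 of 170 members higher and 0 lower (11 higher when adjusted over the list alone, list adjusted p = 0.433). Genes of innate immunity and detoxification had 11 of 279 higher and 5 lower, the same as adjusted over the list alone, and chemosensory receptor genes 7 of 711 higher and 3 lower, against 3 and 1 when adjusted over the list alone (list adjusted p = 0.877 and 0.304). Of the PRC2 genes measured, mes-3 rose by 0.47 (SE 0.089, n = 4) and mes-2 fell, both also when adjusted over the list alone. No oocyte, gonadal sheath or early embryonic gene was called over all genes or over those lists alone. Examples were perm-4 with -0.30 and mei-2 with 0.30 among oocyte genes, inx-9 with -0.20 and tnt-4 with -0.31 among sheath genes, and hlh-27 with -0.22 and med-1 with 0.19 among embryonic genes (list adjusted p = 0.877 each). The sheath list had a median of 0.014, a mean of -0.036 and a downward test, and the embryonic list a median of -0.02, a mean of 0.049 and a downward test.

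The mes-4 comparison addresses which genes depend on the H3 lysine 36 methyltransferase, and whether the X chromosome and autosomes respond alike. X-linked genes dominated the rise. bra-1 rose by 2.24 (SE 0.21, n = 4, limma adjusted p = 2.5e-04), rgs-6, a regulator of G protein signalling, by 2.18 (SE 0.26, n = 4), vps-52, a vesicle tethering gene, by 2.05 (SE 0.30, n = 4), egl-6, a neuropeptide receptor gene, by 2.00 (SE 0.29, n = 4) and apm-3, an adaptor complex subunit, by 1.91 (SE 0.26, n = 4). All of these lie on X, and of the 8 highest named genes 7 do. Among autosomal genes ulp-5, a SUMO protease gene, fell to -1.99 (SE 0.13, n = 4, adjusted p = 7.7e-05), wht-2, an ABC transporter gene, to -1.98 (SE 0.16, n = 4), eri-7, which acts in RNA interference, to -1.52 (SE 0.15, n = 4), and tdrd-3, a Tudor domain gene, to -1.35 (SE 0.13, n = 4). gld-1, which encodes a translational repressor needed for oocyte development, fell to -0.63 (SE 0.085, n = 4, adjusted p = 0.00194). The mes-4 probe had a value of 0.63 (SE 0.24, adjusted p = 0.227) and the mes-2 probe -0.21 (SE 0.20, adjusted p = 0.792). The labels give no allele, so whether the mes-4 probe could report the lesion is unknown.

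In mes-4, 504 genes passed the threshold, 325 higher and 179 lower, with 135 and 38 of them differing more than 2-fold. X held 193 of 324 higher genes with a known chromosome (59.6%, against 13.2% of genes tested, odds ratio 10.8, Fisher's exact adjusted p = 4.0e-87) and 4 of 179 lower genes (2.2%, adjusted p = 8.1e-07). Chromosome I held 49 of the 179 lower genes (27.4%, against 15.7% of genes tested, adjusted p = 1.3e-04). Without mes-4 replicate 1, 2, 3 or 4 the count of called genes was 218, 250, 328 or 280, and X held between 55.6% and 61.9% of the higher genes when any of the 12 arrays was left out, but 34.3% without the 3 arrays at the high end of the residual axis. The count was 283 without the dye term and 879 after scaling of the arrays.

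**Figure D2:**
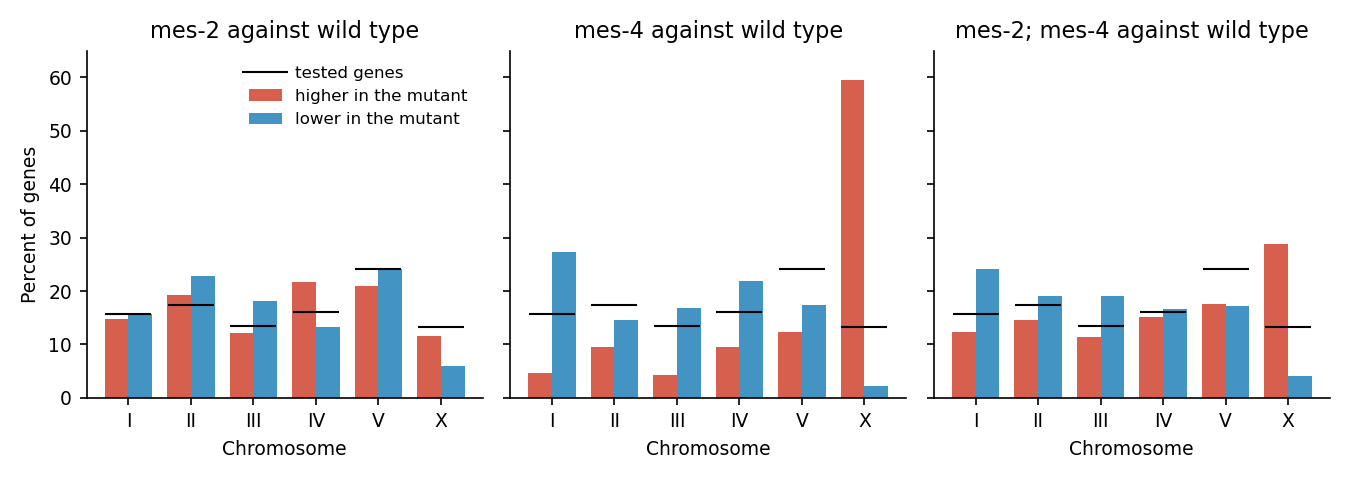
Percent of called genes on each chromosome (vertical axis), for genes higher and genes lower in each mutant, with a line for the percent of tested genes. X held 59.6% of the genes higher in mes-4 and 28.9% of those higher in the double mutant, against 13.2% of genes tested.

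The median over all X-linked genes exceeded the autosomal median in mes-4 by 0.14 ± 0.092 (SD, n = 4) on the log2 scale, above 0 on 4 of 4 arrays. The exact sign-flip p was the smallest that 4 arrays allow, which lies above 0.05. Arrays with mutant RNA in Cy5 averaged 0.065 and those with mutant RNA in Cy3 averaged 0.215. X-linked genes against autosomal genes passed camera with p = 2.3e-11 and with p = 0.0091 at an estimated correlation. In mes-2 the excess was 0.043 ± 0.11 (SD, n = 4, 2 of 4 arrays above 0, exact p = 0.5, camera p = 0.329), with -0.05 for Cy5 and 0.135 for Cy3. In the double mutant it was 0.15 ± 0.121 (SD, n = 4, 4 of 4 arrays above 0, again the smallest exact p possible), with 0.06 for Cy5 and 0.24 for Cy3, and camera gave p = 7.1e-09 and p = 0.02 with an estimated correlation. Exact permutation tests of 4 against 4 arrays gave p = 0.257 for mes-4 minus mes-2 (difference 0.098), 0.257 for the double mutant minus mes-2 (0.107) and 0.971 for the double mutant minus mes-4 (0.01), with adjusted p of 0.386, 0.386 and 0.971. Within Cy5 and within Cy3 arrays the differences were 0.115 and 0.08 for mes-4 minus mes-2, 0.11 and 0.105 for the double mutant minus mes-2, and -0.005 and 0.025 for the double mutant minus mes-4. Exact permutations within each dye, chosen after the values were seen, gave p = 0.0556, 0.0556 and 0.944 (adjusted p = 0.0833, 0.0833 and 0.944), where 0.0556 is the smallest that 36 permutations allow. With means over genes in place of medians, the double mutant minus mes-2 was 0.293 and mes-4 minus mes-2 was 0.18, each with an exact p of 0.0286, the smallest possible, and the double mutant minus mes-4 was 0.113 (exact p = 0.2).

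**Figure D3:**
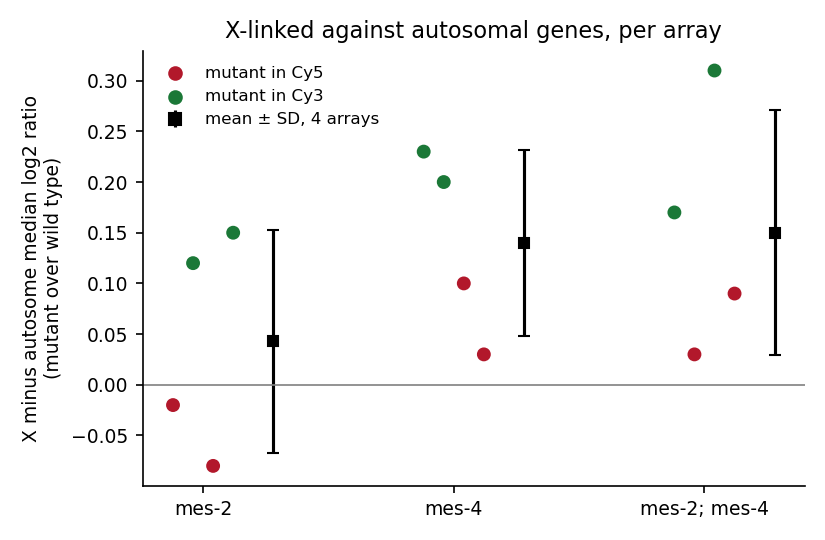
Median log2 ratio of X-linked genes minus that of autosomal genes (vertical axis) on each array, coloured by the dye of the mutant RNA, with the mean and SD of 4 arrays per mutant. All arrays of mes-4 and of the double mutant lie above 0, and in every mutant the Cy3 arrays lie above the Cy5 arrays.

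Intestinal genes fell as a list in mes-4 (camera adjusted p = 2.1e-05, adjusted p = 0.798 with an estimated correlation), with 0 of 21 members called over all genes and 9 lower when adjusted over the list alone. The yolk protein genes vit-1 and vit-4 had -1.16 (SE 0.32, adjusted p = 0.0746) and -0.60 (SE 0.17, adjusted p = 0.0864). The list median was -1.29 and -1.13 on the arrays with mutant RNA in Cy3 and -0.08 and -0.17 on those with mutant RNA in Cy5. Collagen genes fell as a list (adjusted p = 3.3e-05, adjusted p = 0.798 with an estimated correlation), with 0 of 109 members called over all genes and 0 when adjusted over the list alone, and col-81 and col-39 had -0.75 (SE 0.19) and -0.69 (SE 0.18). The major sperm protein family fell as a list (adjusted p = 0.0245, adjusted p = 0.916 with an estimated correlation), again with 0 of 39 members called over all genes and 0 over the list alone, and ssp-35 and ssp-33 had -0.82 (SE 0.35) and -0.81 (SE 0.36). Histone genes rose as a list (adjusted p = 6.6e-05, adjusted p = 0.798 with an estimated correlation), with 1 of 31 called, his-8 at 0.69 (SE 0.14, n = 4), 3 higher when adjusted over the list alone, and his-62 at 0.66 (SE 0.16, adjusted p = 0.0503). The sperm protein list lost the call without mes-4 replicate 2 or 4 and with the replicate number as a block, and the histone list without mes-4 replicate 3.

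Of the sperm genes outside that family 2 of 17 fell in mes-4 (2 when adjusted over the list alone), spe-15 to -1.0 (SE 0.16, n = 4) and spe-44, which controls sperm gene transcription, to -0.53 (SE 0.13, n = 4), although spe-44 was not called in 14 of 26 other settings. The list did not pass (adjusted p = 0.131). Among gonadal sheath genes nmy-1, a non-muscle myosin gene on X, rose by 0.42 (SE 0.08, n = 4) and fos-1 had 0.49 (SE 0.15, adjusted p = 0.103), with 1 of 10 members called over all genes and 2 when adjusted over the list alone (list adjusted p = 0.479). No oocyte or early embryonic gene was called over all genes or over those lists alone, with cav-1 at 0.50 and gna-2 at -0.32 among oocyte genes (list adjusted p = 0.84), and sdz-38 at 1.79 and nhr-2 at 0.26 among embryonic genes (list adjusted p = 0.309). The neuronal gene unc-119 rose by 1.57 (SE 0.124, n = 4), the only 1 of 20 neuronal genes called over all genes or over the list alone, and the mitochondrial gene gas-1 by 1.76 (SE 0.189, n = 4), the only 1 of 31.

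The double mutant addresses what happens when both genes are mutated, with germ lines selected for proliferation and oocytes. As the labels give no allele, whether both enzymes were absent is unknown. tbb-6, a beta tubulin gene, rose by 5.69 (SE 0.62, n = 4, limma adjusted p = 1.3e-04), bra-1 by 4.18 (SE 0.21, n = 4), gst-38, a glutathione S-transferase gene, by 4.11 (SE 0.33, n = 3), egl-6 by 4.00 (SE 0.29, n = 4), coh-1, a cohesin gene, by 3.77 (SE 0.36, n = 4) and aly-1, an RNA export gene, by 3.42 (SE 0.19, n = 4). The mes-2 probe fell to -2.49 (SE 0.20, n = 4, adjusted p = 1.5e-05) and the mes-4 probe had -0.03 (SE 0.24, adjusted p = 0.956). In 1 of 26 other settings, without the 3 arrays at the high end of the residual axis, the mes-4 probe passed the threshold as higher. tofu-2, a gene of piRNA production, fell to -1.94 (SE 0.13, n = 4), wht-2 to -1.90 (SE 0.16, n = 4), haf-6, an ABC transporter gene, to -2.42 (SE 0.48, n = 4) and nep-8, a neprilysin gene, to -1.85 (SE 0.20, n = 3). Values of tbb-6 ranged from 3.4 to 8.54 over the 4 arrays.

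In the double mutant 2046 genes passed the threshold, 1240 higher and 806 lower, with 434 and 151 differing more than 2-fold. Without the 3 arrays at the high end of the residual axis the majority turned, with 1275 higher and 1341 lower. X held 358 of 1237 higher genes (28.9%, against 13.2% of genes tested, odds ratio 3.12, Fisher's exact adjusted p = 1.1e-52) and 32 of 801 lower genes (4%, adjusted p = 1.1e-18). Chromosome I held 193 of the 801 lower genes (24.1%, adjusted p = 5.5e-10) and chromosome III 152 (19%, adjusted p = 1.8e-05). Fitted on its own 4 arrays the double mutant had 173 called genes, 152 higher and 21 lower, and X held 46.7% of the higher genes. In the joint fit without the 2 arrays at the low end of the residual axis X held 19% of the higher genes. The count was 1294 without replicate 4 of the double mutant, 1301 without the dye term and 1302 with an added 1.5-fold threshold.

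Histone genes rose as a list in the double mutant (camera adjusted p = 8.9e-08, adjusted p = 0.964 with an estimated correlation), with 20 of 31 members higher, 0 lower and 11 not past the test, and 23 higher when adjusted over the list alone. his-8 rose by 1.78 (SE 0.14, n = 4), his-62 by 1.54 (SE 0.16, n = 4), his-4 by 1.17 (SE 0.202, n = 4) and the linker histone gene hil-1 by 0.90, while the centromeric histone gene hcp-3 had 0.07. This was the only list past the test at the preset correlation with all arrays. Without double mutant replicate 2 the germ granule, meiotic, cell cycle and mitochondrial lists passed as well. Mitochondrial respiration genes had 9 of 31 members higher and 1 lower, the same as adjusted over the list alone (list adjusted p = 0.0755), among them gas-1 by 2.51 (SE 0.189, n = 4) and nuo-6 by 0.86 (SE 0.188, n = 4). Of 26 germ granule and germline RNA regulators 2 rose and 6 fell, the same as adjusted over the list alone (list adjusted p = 0.214). meg-1 rose by 0.90 (SE 0.216, n = 4), and cgh-1, fbf-1 and fbf-2 fell to -1.10 (SE 0.143), -0.95 (SE 0.178) and -0.87 (SE 0.158, n = 4 each), the last a pair of genes for Pumilio-type regulators of germline stem cells. Of 31 meiotic chromosome genes 1 rose and 4 fell, the same as adjusted over the list alone (list adjusted p = 0.193). syp-3, of the synaptonemal complex, rose by 0.92 (SE 0.158), and him-19, rec-8, the meiotic cohesin subunit, and htp-3, of the chromosome axis, fell to -1.74 (SE 0.211), -1.27 (SE 0.202) and -0.98 (SE 0.163, n = 4 each).

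**Figure D4:**
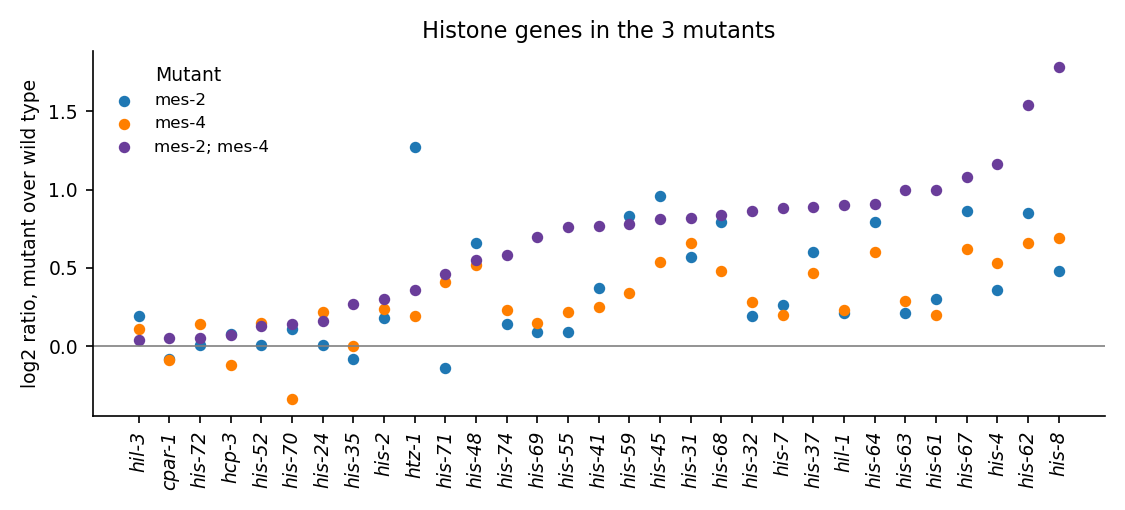
Log2 ratio of mutant over wild type (vertical axis) of each of 31 histone genes in the 3 mutants, ordered by the double mutant. In the double mutant 20 genes passed the threshold as higher and 0 as lower, and his-8 had the highest value at 1.78.

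Small RNA genes in the double mutant had 1 of 30 members higher and 4 lower (2 and 5 when adjusted over the list alone, list adjusted p = 0.518), with wago-1, an Argonaute gene, at -1.02 (SE 0.249, n = 4) and alg-1 at 0.85 (SE 0.156, n = 4). Sperm genes outside the major sperm protein family had 1 of 17 higher and 3 lower (2 and 6 when adjusted over the list alone, list adjusted p = 0.311), with spe-15 falling to -1.40 (SE 0.16, n = 4) and spe-44 to -0.62 (SE 0.13, n = 4). Oocyte genes had 2 of 23 members lower, spn-4 at -0.46 (SE 0.10, n = 4) and cbd-1 at -0.82 (SE 0.24, n = 4), and 1 lower when adjusted over the list alone (list adjusted p = 0.456), although cbd-1 was not called in 12 of 26 other settings. No sheath, early embryonic, intestinal or major sperm protein gene was called over all genes or over those lists alone, and lim-7 and inx-8 had -0.24 and -0.25 among sheath genes, and hlh-29 and sdz-38 had 0.74 and 1.10 among embryonic genes (list adjusted p = 0.845 and 0.994). The sheath list had a median of 0.006, a mean of -0.025 and a downward test. The dosage compensation list had 3 of 12 members higher, sdc-1 by 1.65 (SE 0.36, n = 4), her-1 by 0.74 (SE 0.137, n = 4) and sdc-3 by 0.36 (SE 0.085, n = 4), with 3 higher and 1 lower when adjusted over the list alone (list adjusted p = 0.617). The PRC2 gene mes-3 rose by 0.91 (SE 0.089, n = 4).

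The overlap of the mutants addresses whether the enzymes affect the same genes. Of the genes higher in mes-4, 272 of 325 (83.7%) were also higher in the double mutant, 171 of them on X, against 31.3 for independent calls (Fisher's exact p = 2.8e-230). Of the genes lower in mes-4, 114 of 179 were lower in the double mutant, against 11.2 for independent calls. The mes-2 and double mutants shared 241 higher and 56 lower genes, against 48.9 and 10.5, and mes-2 and mes-4 shared 138 genes called in the same direction, 34 of them lower, against 12.8 higher and 2.33 lower genes for independent calls. All 3 mutants shared 87 higher and 26 lower genes. Opposite calls numbered 15 for mes-2 and mes-4, 24 for mes-2 and the double mutant and 2 for mes-4 and the double mutant. Log2 ratios correlated across genes at r = 0.623 for mes-4 and the double mutant, 0.375 for mes-2 and the double mutant and 0.283 for mes-2 and mes-4. Each array had its own wild-type channel, and the labels do not say whether wild-type RNA of the same strain was shared between arrays of mes-2 and the double mutant. All 3 mutants were also tested in a single fit with a shared spread per gene, so a gene with a small spread is more easily called in each. The values for independent calls and the Fisher's exact p ignore both, so the excess over them does not measure shared effects alone.

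**Figure D5:**
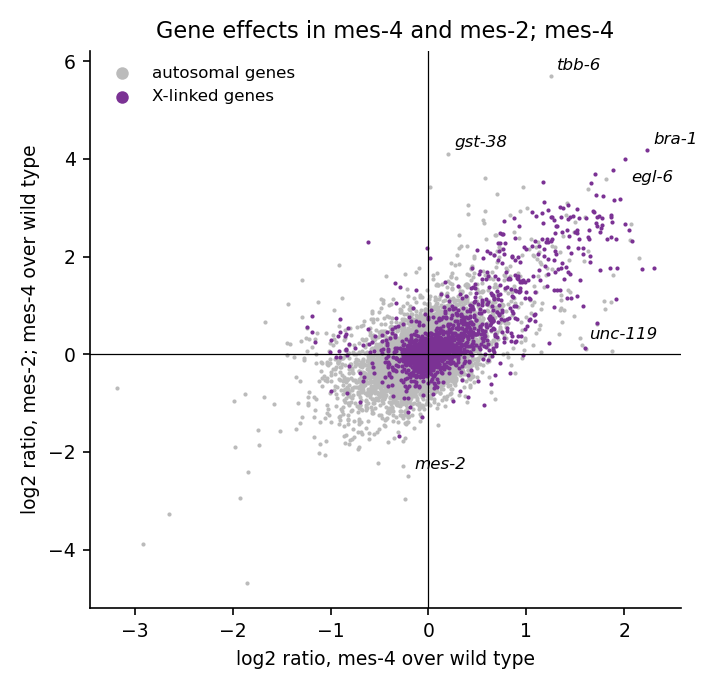
Log2 ratio of each tested gene in mes-4 (horizontal axis) and in the double mutant (vertical axis), with X-linked genes in purple. bra-1 had 2.24 in mes-4 and 4.18 in the double mutant, and unc-119 had 1.57 and 0.19.

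Genes called in a single mutant were followed into the double mutant. The 325 genes higher in mes-4 had a median of 0.85 in mes-4 and 1.28 in the double mutant, and 222 of them had the larger value in the double mutant. The 508 genes higher in mes-2 had a median of 0.92 in mes-2 and 0.49 in the double mutant, and 137 of them were larger there. For genes lower in mes-2 the medians were -0.64 and -0.22, and for genes lower in mes-4 they were -0.68 and -0.46. Genes picked for passing in a single mutant are expected to lie closer to 0 elsewhere, and these medians carry no test. The SD over all probes was 0.508 to 0.556 on the mes-4 arrays and 0.629 to 0.806 on the double mutant arrays. Larger values in the double mutant than in mes-4 can follow in part from this wider spread. The wild types of these 2 groups also differed, N2 and unc-4(e120).

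Direct tests of the double mutant against mes-2 asked what the mes-4 mutation adds, which the selection of double mutant germ lines is not separated from. tbb-6 was higher by 5.65 (SE 0.88), aly-1 by 4.02 (SE 0.27), gst-38 by 3.85 (SE 0.43) and fbxa-170, on X, by 4.49 (SE 0.93), and homt-1, low in mes-2, was higher by 4.27 (SE 0.33). nrsn-1, nas-30 and cls-1, all high in mes-2, differed by -2.73 (SE 0.41), -2.58 (SE 0.47) and -2.23 (SE 0.53). In all, 798 genes passed, 460 higher and 338 lower in the double mutant, a majority that turned to 685 higher and 724 lower without the 3 arrays at the high end of the residual axis. X held 167 of 459 higher genes (36.4%, Fisher's exact adjusted p = 1.1e-36) and 4 of 336 lower genes. The share of higher genes on X was 55% without the dye term and 16.9% without the 2 arrays at the low end of the residual axis. Ribosomal and histone genes were higher as lists (adjusted p = 0.0318 each, 0.981 each with an estimated correlation) and sperm genes outside the major sperm protein family and cell cycle genes were lower (adjusted p = 0.0318 and 0.04, with 0.229 and 0.981 with an estimated correlation). Of these lists' members 1 of 67, 1 of 31, 1 of 17 and 1 of 30 were called over all genes, and 1, 1, 1 and 0 when adjusted over the list alone. The count was 465, 502, 526 or 528 without mes-2 replicate 1, 2, 3 or 4, 494 without replicate 4 of the double mutant, 367 without the dye term and 330 on the 8 arrays compared.

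The double mutant against mes-4 asked what the mes-2 mutation adds. The ratios of the double mutant are against unc-4(e120) and those of mes-4 against N2, so a strain difference, and the selection of double mutant germ lines, are not separated from that mutation. gst-38 was higher by 3.91 (SE 0.43), nhr-107, a nuclear hormone receptor gene, by 2.65 (SE 0.34) and aly-1 by 2.45 (SE 0.27). The mes-2 probe differed by -2.28 (SE 0.28) and unc-119, a gene high in mes-4, by -1.38 (SE 0.18). In all, 229 genes passed, 188 higher and 41 lower in the double mutant, and X held 55 of 188 higher genes (29.3%, Fisher's exact adjusted p = 7.1e-08). That share was 44.9% without the 3 arrays at the high end of the residual axis and 12.7% without the 2 at its low end, where it did not exceed the 13.2% of genes tested. Intestinal, collagen, mitochondrial and histone genes were higher as lists (adjusted p = 9.0e-04, 0.0377, 0.0364 and 9.0e-04) and small RNA and cell cycle genes lower (0.0364 and 0.0308), each with adjusted p = 0.797 with an estimated correlation. Of their members 1 histone gene of 31 was called over all genes and 2 when adjusted over the list alone, and 0 of the other lists either way. The count was 81, 75 or 108 without mes-4 replicate 1, 2 or 4, 93 without replicate 4 of the double mutant, 67 without the dye term, 85 on the 8 arrays compared and 91 after scaling.

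Between mes-4 and mes-2, 252 genes passed, 84 higher and 168 lower in mes-4, and here too the wild types were N2 and unc-4(e120), a difference not separated from the mutations. The F-box genes fbxa-193 and fbxa-108 were higher in mes-4 by 4.24 (SE 0.36) and 2.91 (SE 0.33), homt-1 by 4.19 (SE 0.33) and rnh-1.3, a ribonuclease H gene, by 3.64 (SE 0.34). unc-31 differed by -2.55 (SE 0.31), ndx-2 by -2.47 (SE 0.24) and the small heat shock gene hsp-16.41 by -3.61 (SE 0.74), although hsp-16.41 was not called in 10 of 26 other settings. X held 37 of 84 higher genes (44%, Fisher's exact adjusted p = 4.3e-11) and 7 of 168 lower genes (adjusted p = 5.1e-04). Lower in mes-4 as lists were intestinal (adjusted p = 6.9e-05), sperm (0.0063), collagen (0.013) and major sperm protein genes (0.0392), with adjusted p of 0.987, 0.152, 0.987 and 0.987 with an estimated correlation. Of their members 1 of 21, 2 of 17, 0 of 109 and 0 of 39 were called over all genes, and 3, 2, 0 and 0 when adjusted over the list alone. The count was 159 or 139 without mes-2 replicate 1 or 2, 115, 127, 164 or 164 without mes-4 replicate 1, 2, 3 or 4, 117 without the dye term, 386 on the 8 arrays compared and 419 after scaling.

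The departure of the double mutant from the sum of the single mutants asks whether the effects add on the log2 scale, and it too mixes ratios against both wild types and holds the selection of double mutant germ lines. homt-1, with -4.65 in mes-2 and -0.46 in mes-4, had -0.38 in the double mutant, a departure of 4.72 (SE 0.40, limma adjusted p = 0.00112). The F-box genes fbxa-192, fbxa-193 and fbxa-108 departed by 4.14 (SE 0.28), 3.88 (SE 0.45) and 3.83 (SE 0.41), and gst-38 by 3.65 (SE 0.51). unc-31, with 2.90, 0.34 and 0.84 in the 3 mutants, departed by -2.40 (SE 0.38) and dpy-31, a procollagen processing protease gene, with 2.19, 0.08 and 0.35, by -1.92 (SE 0.26). In all, 159 genes passed, 88 higher and 71 lower than the sum, a majority that turned without the dye term (16 and 25), after scaling (95 and 118) and without mes-2 replicate 1 (45 and 46), mes-2 replicate 4 (55 and 62) or mes-4 replicate 2 (44 and 45). X held 17 of 88 higher genes (19.3%, Fisher's exact adjusted p = 0.474). That share lay above or below the 13.2% of genes tested depending on the setting, as given in the section on processing. Intestinal, collagen and ribosomal genes departed upwards as lists (adjusted p = 0.0399, 0.0399 and 0.0101) and small RNA and cell cycle genes downwards (0.0101 and 0.0205), each with adjusted p = 0.622 with an estimated correlation and with 0 members called over all genes or over the list alone. The count was 91, 91 or 98 without mes-2 replicate 1, 2 or 3, 82, 89 or 84 without mes-4 replicate 1, 2 or 4, 86 without replicate 4 of the double mutant, and 41 without the dye term.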

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

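The tests of dye, of RNA from other tissues, of the wild-type strain, of neighbouring genes, of a single mes-2 array, of germline composition and of missing spots were chosen after the result was seen, and those of gene span and of other splits of the arrays before. Among 171 groups of 4 values tested, 11 held a value far from the others, and chance gives about 1 group in 20.

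X-linked genes made up 59.6% of the genes higher in mes-4, and 34.3% without the 3 arrays at the high end of the residual axis described below. A dye effect, RNA from intestine and the N2 wild type were each argued against, for intestine by a narrow margin. RNA from sheath was argued against only for the X genes called higher, and not for the X excess over all genes. The intestinal list median was -1.29 and -1.13 on the mes-4 arrays with mutant RNA in Cy3, but -0.08 and -0.17 in Cy5. RNA of other somatic tissues was not settled: 13 of 20 neuronal genes lay above 0 in mes-4, against 22 of 109 collagen and 7 of 23 muscle genes. On X lay 9 of the 20 neuronal, 16 of the 109 collagen and 9 of the 23 muscle genes. The neuronal count is thus not independent of the rise of X-linked genes. X held 60.5% (exact 95% interval 53.4% to 67.3%) of the 200 genes highest over the mes-4 arrays with mutant RNA in Cy5, where the X excess was smaller, against 13.2% of genes tested. The highest sheath marker had 0.49 (SE 0.15) against a median of 1.06 for the 193 X genes called higher. These genes were picked for passing on the same arrays, which raises their median. On the double mutant arrays they had a median of 1.6, against 0.006 for the sheath list. The median of all X-linked genes exceeded the autosomal median in mes-4 by 0.14 ± 0.092 (SD, n = 4). The sheath list median of 0.115 ± 0.129 (SD, n = 4) was close to that, so sheath RNA stays open for this excess. The intestinal list averaged -0.667 ± 0.631 (SD, n = 4), with vit-2 at -1.01 and vit-6 at -0.98. In the double mutant, whose wild type was unc-4(e120), 98.4% of the 193 X genes were positive, against 67.1% of all tested X genes. Loss of MES-4 may raise X-linked genes, a hypothesis found and tested on the same data that stays open, since 166 of the 193 were positive in mes-2 too (median 0.36, 42 called), and the authors' normalization and spot filtering are unknown and stayed untested.

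In mes-2, 102 genes passed the threshold and also departed from additivity, and since the departure contains the same mes-2 arrays with the sign turned, noise in them adds to this number. A single mes-2 array as the whole source was argued against, since with all genes called again 56, 53, 56 or 73 genes passed both tests without mes-2 replicate 1, 2, 3 or 4. Chromosome segments that differ between the mes-2 strain and its wild type stayed open: 5 pairs of these genes were neighbours, against a 95th percentile of 2 for random sets of tested genes and of 4 for random sets of mes-2 calls, the latter comparison added once the first value was known. Neighbours are not particular to this strain, since all called genes made 76 neighbouring pairs in mes-2, 62 in mes-4 and 419 in the double mutant, against medians of 35, 20 and 324 for random sets, and the 5 pairs included F-box genes of similar sequence, which can share a probe's signal, and homt-1 with nlp-40, which changed in opposite directions. The test sees only segments in which neighbouring tested genes both pass, so it does not bound the share of changes due to such segments. An effect of the added mes-4 mutation also stays open and untested.

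After the fit, 47% of the residual variance lay along a single axis, with mes-4 replicate 3 and double mutant replicates 1 and 4 at its high end and double mutant replicates 2 and 3 at its low end. A dye effect that differs between groups was argued against, since a residual correlation of 0.67 in size between arrays of different groups remained with a dye term per group, and so were spots without a value (Spearman rho -0.04, permutation p = 0.904, and Pearson r -0.05, permutation p = 0.876, across 12 arrays, and r 0.2 without the 2 farthest arrays). Germline composition of the dissected gonads stayed open, with germ granule genes at percentile 0.04 of random lists on this axis, and at 0.26 among lists of matched gene span, while the histone, intestinal, collagen, major sperm protein, ribosomal and mitochondrial lists, which passed tests in the comparisons, lay at percentile 100 and the small RNA and cell cycle lists at 0. Gene length bias stayed open, with a Spearman correlation of -0.41 across genes with gene span, and genes are not independent replicates. Either may be the source, and the design gives no biological group that follows this axis.

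Other splits of the arrays were counted for each comparison. Within the single groups, 1 of 8 relabellings gave as many genes in each case, the real one, with 676 against at most 1 in mes-2, 504 against 0 in mes-4 and 2046 against at most 31 in the double mutant, and 8 relabellings are too few for a share under 0.05. For the double mutant against mes-2, 1 of 35 splits gave as many, the real one (798 against at most 0). For mes-4 against mes-2, 1 of 35 did too (252 against at most 2). These are the smallest shares that 35 splits allow, and they argue against chance without excluding it. Every other split mixes the 2 mutants, so a difference between them adds to the spread and low counts are likely. Chance is not argued against for the double mutant against mes-4, where 3 of 35 splits gave as many as 229 and the highest other gave 1090, which points to a structure of the samples. For the departure from additivity 3 of 100 drawn regroupings, the real one included, gave as many as 159. The highest other gave 627, which points to a structure too. As another grouping of the arrays gave more genes than the real one, chance is not excluded here. These counts also do not separate the mutations from the wild-type strain, which was N2 for mes-4 and unc-4(e120) for the others, or from the selection of double mutant germ lines.

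In mes-2, values far from the other arrays were the collagen list median of -0.38 in replicate 3 (others 0.09 to 0.15), the histone list median of 0.12 in replicate 1 (others 0.37 to 0.42), mei-2 at 0.46 in replicate 3, rpl-37.2 at -1.24 in replicate 4 and sre-44 at 6.34 in replicate 2. In mes-4 they were the meiotic list median of 0.18 in replicate 4 (others -0.14 to -0.12), apm-3 at 2.69, egl-6 at 2.74 and spe-44 at -0.25, all in replicate 4. In the double mutant, replicate 3 had 5193 probes without a value (others 2704 to 2985) and tofu-2 at -2.66.

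Differences between mutants past limma's test of the difference were listed for named genes. The double mutant differed from mes-2 by 5.65 for tbb-6, 4.49 for fbxa-170, 4.27 for homt-1, 4.02 for aly-1, 3.85 for gst-38, -2.73 for nrsn-1, -2.58 for nas-30, -2.26 for nsph-3.1, -2.23 for cls-1 and -2.15 for gcy-19. It differed from mes-4 by 4.44 for tbb-6, 3.91 for gst-38, 2.91 for ttr-6, 2.65 for nhr-107, 2.45 for aly-1, -2.28 for mes-2, -1.81 for rnh-1.3, -1.47 for elpc-2, and -1.38 for both lin-25 and unc-119. The mes-4 mutant differed from mes-2 by 4.24 for fbxa-193, 4.19 for homt-1, 3.64 for rnh-1.3, 2.91 for fbxa-108, 2.59 for mes-2, -3.61 for hsp-16.41, -3.09 for cls-1, -2.55 for unc-31, -2.47 for ndx-2 and -2.42 for gcy-19. Departures from additivity were 4.72 for homt-1, 4.14 for fbxa-192, 3.88 for fbxa-193, 3.83 for fbxa-108, 3.65 for gst-38, -3.16 for citk-1, -2.40 for unc-31, -2.24 for gpa-1, -2.09 for srh-16 and -1.92 for dpy-31. Some of these calls were fragile. Against mes-4, lin-25 was lost in 18 and tbb-6 in 13 of 26 other settings. For mes-4 minus mes-2, gcy-19 was lost in 12 of 22 and hsp-16.41 in 10 of 26. The departures of citk-1 and gpa-1 were each lost in 12 of 25, and that of homt-1 in 0. fbxa-170 had 1.64, -4.62 and -2.47 on the mes-2 arrays with a value.

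Lists whose difference passed camera at the preset correlation, 0 of which passed with an estimated correlation, had these median differences. The double mutant minus mes-2 had 0.34 for ribosomal and 0.25 for histone genes, -0.22 for sperm genes outside the major sperm protein family and -0.25 for cell cycle genes. Minus mes-4 it had 0.76 for intestinal, 0.17 for collagen, 0.31 for mitochondrial and 0.36 for histone genes, and -0.19 for both small RNA and cell cycle genes. For mes-4 minus mes-2 they were -0.39 for major sperm protein, -0.83 for intestinal, -0.19 for collagen and -0.16 for other sperm genes. For the departure from additivity they were 0.64 for intestinal, 0.25 for collagen and 0.40 for ribosomal genes, -0.27 for small RNA and -0.28 for cell cycle genes.

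Probes that name no gene, not used in the comparisons, also carried signal. Of 4027 such probes tested, 155 passed the threshold in mes-2 (110 higher, 45 lower), 131 in mes-4 (91 higher, 40 lower) and 510 in the double mutant (265 higher, 245 lower).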

How the results depend on the processing

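The fits with a dye term per group or with arrays left out for their residuals, and permutations within dye, were chosen after seeing the data, and the other settings before. Of 103 named results past the threshold, 65 stayed past it in every setting run, 38 lost it in at least 1 of up to 26 settings and 0 reversed. With a dye term per group, centring, other filters on missing values, each probe alone and robust moderation, every count of called genes stayed within 1.5 times the reported count.

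Without the dye term the counts were 402 in mes-2, 283 in mes-4, 1301 in the double mutant, 367 for the double mutant minus mes-2, 67 for it minus mes-4, 117 for mes-4 minus mes-2 and 41 for the departure, and 4125 genes had passed for dye. The shared calls then numbered 348 in at least 1 pair of mutants against 595, with 63 for mes-2 and mes-4, 172 for mes-2 and the double mutant and 219 for mes-4 and the double mutant. At an adjusted p under 0.1 the shared calls were 223 for mes-2 and mes-4 and 588 for mes-4 and the double mutant, against 138 and 386, as a looser threshold calls more genes.

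With only the groups compared, the counts were 499 in mes-2, 516 in mes-4, 173 in the double mutant, 330 and 85 for it minus mes-2 and minus mes-4, and 386 for mes-4 minus mes-2, and of the 173 genes 171 were shared with the reported calls. After scaling the counts were 879 in mes-4, 91 for the double mutant minus mes-4 and 419 for mes-4 minus mes-2, and the departure split into 95 higher and 118 lower genes. Its majority also turned to lower genes without the dye term (16 and 25) and without mes-2 replicate 1 (45 and 46), mes-2 replicate 4 (55 and 62) or mes-4 replicate 2 (44 and 45). An added 1.5-fold threshold left 1302 genes in the double mutant by its construction. The cause was not tested for the changes without the dye term, with only the groups compared or after scaling. The X share of higher genes moved over 1.5 times with only the groups compared in mes-2 (18.3% against 11.5%) and the double mutant (46.7% against 28.9%), without the dye term for the double mutant minus mes-2 (55% against 36.4%) and the departure (31.2% against 19.3%), and after scaling for the departure (10.5%).

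The replicate numbers do not pair the arrays: residuals of the 12 same-numbered pairs correlated from -0.448 to 0.479. With the number as a block the counts were 323 in mes-4, 453, 101 and 115 for the differences of the double mutant from mes-2, of it from mes-4 and of mes-4 from mes-2, and 44 for the departure, where the X share of higher genes was 8.3%, and the cause was not tested.

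Without the 3 arrays at the high end of the residual axis the counts were 1161 in mes-2, 1518 in mes-4, 1409 for the double mutant minus mes-2, 382 for it minus mes-4 and 697 for mes-4 minus mes-2, and the mes-4 gene in the double mutant moved from -0.03 to 0.55, past limma's threshold. The majority then turned to lower genes, with 1275 higher and 1341 lower in the double mutant and 685 and 724 for it minus mes-2. Without the 2 arrays at its low end they were 886 in mes-4, 1872, 1133 and 429 for those differences and 806 for the departure. The X share of higher genes without the 3 arrays was 18.2% in mes-2, 34.3% in mes-4, 44.9% for the double mutant minus mes-4 and 40.7% for the departure, and without the 2 arrays 19% in the double mutant, 16.9% and 12.7% for it minus mes-2 and minus mes-4 and 9.2% for the departure. These arrays were picked by their residuals, so the remaining spread is understated and the larger counts are no evidence of more changed genes.

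For the X excess over autosomes, means over genes gave 0.226 in mes-4, 0.339 in the double mutant, 0.293 for it minus mes-2, 0.113 for it minus mes-4 (exact permutation p = 0.2) and 0.18 for mes-4 minus mes-2, and scaling gave -0.03 for the double mutant minus mes-4 (exact permutation p = 0.657). The cause was not tested. Exact permutations within dye gave a p above 0.05 for every difference, as 0.0556 is the smallest possible. With an estimated correlation 0 lists passed in mes-2, 0 in mes-4 and 0 in the double mutant. The estimates were 0.476 for histone, 0.428 for intestinal and 0.667 for major sperm protein genes, against the preset 0.01. For ribosomal, collagen and dosage compensation genes they were 0.336, 0.245 and 0.293. This test also used only the genes with all values, which kept 31 of 31 histone, 39 of 39 major sperm protein and 20 of 21 intestinal genes. A loss of members thus does not account for the lost calls of the histone and major sperm protein lists. In the double mutant 2 lists passed without the dye term, with arrays centred on autosomal genes and after scaling, the added list being mitochondrial respiration.

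Leaving out each of the 12 arrays gave 352 to 794 genes in mes-2, 218 to 668 in mes-4, 1294 to 2152 in the double mutant, 465 to 833 for it minus mes-2, 75 to 258 for it minus mes-4, 115 to 342 for mes-4 minus mes-2 and 82 to 190 for the departure. The X excess ran from 0.007 to 0.083 in mes-2, 0.11 to 0.177 in mes-4 and 0.097 to 0.19 in the double mutant. Its differences ran from 0.054 to 0.148 for the double mutant minus mes-2, -0.043 to 0.05 for it minus mes-4, negative without mes-4 replicate 3 (-0.003), mes-4 replicate 4 (-0.027) or double mutant replicate 3 (-0.043), and 0.057 to 0.134 for mes-4 minus mes-2. Between 1 and 5 lists passed in mes-2, 3 and 5 in mes-4 and 1 and 5 in the double mutant, where histones passed each time. Signal over background was not analysed here, since ratios alone were read.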

Other observations

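The sign-flip test over all arrays and the comparison with lists of matched gene span were chosen after the results were seen. Over all 12 arrays the median of X-linked genes exceeded that of autosomal genes by 0.111 ± 0.11 (SD), with 10 arrays above 0 and an exact sign-flip p of 0.00586. The arrays belong to 3 groups, so this value speaks for the mutants together and not for any of them.

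Across genes, the annotated gene span correlated with the log2 ratio at Spearman rho 0.06 in mes-2, 0.08 in mes-4 and -0.14 in the double mutant, and genes are not independent replicates. Among 10000 random lists of matched gene span, which ignore the correlation within a list, the histone list median lay at percentile 100 in each mutant, although with an estimated correlation the list passed in none (camera adjusted p = 0.917 in mes-2, 0.798 in mes-4 and 0.964 in the double mutant). In mes-2, mes-4 and the double mutant the intestinal list lay at percentiles 97.89, 0 and 76, the collagen list at 23.44, 0 and 0.91, the major sperm protein list at 99.87, 0 and 0 and the ribosomal list at 0, 10.16 and 76.12, and in these mutants none of the lists passed with an estimated correlation.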
